A study of Mus musculus with 6 samples.

How the data were processed

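Single nuclei from snap-frozen pituitaries of 6 male mice of mixed strain, 3 controls and 3 with a gonadotrope-specific conditional knockout of Gata2, were profiled as 1 library per mouse. Groups and mouse numbers were taken from the sample labels. The authors deposited UMI counts per gene and nucleus as filtered barcode matrices, and the values were whole numbers with library totals that differed, with no normalization. Per the submitters' processing notes, Cell Ranger 5.0.0 and the mm10 build were used. The annotation, whether intronic reads were counted, and whether strand was used are not given in the sources used here. The matrix of cKO 17 was not analysed here, so the comparisons rest on 3 control and 2 cKO libraries. Of 32285 genes in the tables, 32158 were matched by identifier to the GRCm38 gene annotation, from which positions were taken.

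Barcodes with at least 500 detected genes and under 5% of UMIs from mitochondrial genes were kept. Doublets were scored in each library against 2 simulated doublets per nucleus by Scrublet's method, with an expected rate of 0.8% per 1000 nuclei. Nuclei above the automatic threshold were removed; where it marked under 0.5% of nuclei, the expected share was removed in its place, which applied only to control 2 and cKO 7 at 1000 genes. At 500 genes this took 1925, 1014 and 1185 nuclei (13.6, 7.33 and 9.01%) from controls 2, 8 and 9 and 1702 and 2531 nuclei (9.05 and 14.9%) from cKO 3 and cKO 7. This left 12274, 12818, 11970, 17099 and 14448 nuclei. The median barcode held 2706, 3929 and 4943 UMIs and 1309, 2193 and 2209 genes in controls 2, 8 and 9, and 2620 and 3004 UMIs and 1609 and 1352 genes in cKO 3 and cKO 7. Its mitochondrial share was 0.229, 0.26, 0.288, 0.108 and 0.199%.

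Log-normalized counts of 2000 variable genes chosen within libraries, 30 principal components, a shared-neighbour graph of 20 neighbours and Leiden clustering at resolution 1 gave the clusters, with no integration of libraries and a fixed seed of 20. Gata2, Fshb, Lhb, Cga, Gnrhr, Grem1, Fst, Tshb and mitochondrial genes were left out of the variable genes. Clusters were named from marker lists fixed before the data were examined, by the highest mean fold of a list's markers within libraries. A named cluster needed 3 markers with a log2 fold of at least 0.5 in at least 5% of its nuclei, and no other list could have more genes among its 10 leading genes. Clusters under 0.6 of the median UMI count with markers of 2 types, clusters of very low UMI count with no marker among the leading genes, and clusters whose score was under 0.5 of the highest of their type, stayed unnamed. These scoring thresholds were set after seeing the data, and names are given as "X-like". A somatotrope-like cluster of 28 nuclei was led by interferon response genes, and a lactotrope-like cluster of 350 nuclei had 2.28 times the median UMI count of its libraries and doublets were not excluded there. The gonadotrope-like clusters had 1.65 and 0.46 times the median UMI count.

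UMIs were summed per library and cell type, since nuclei are not replicates. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3; TMM, filterByExpr), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold, in gonadotropes and in 12 other cell types with at least 20 nuclei in every library. The difference of the fold between gonadotropes and the sum of other endocrine nuclei was tested as an interaction with the library as a block. Counts of nuclei per type were tested with the quasi-likelihood test of edgeR against the total nuclei of each library. TMM, filterByExpr and a dispersion trend were not used there. The shares were also tested with two-sided exact permutation tests, for which 3 against 2 libraries make 10 splits and a smallest p of 0.1. For shares of nuclei with a UMI, each nucleus was thinned to 1000 UMIs, and intervals are exact at 95%; a share of 0 allows up to 3 counts of the total. Intervals and these limits cover counting error only. Fixed gene lists were tested with camera (preset correlation 0.01, and estimated) and fry in limma 3.58.1. The lists were gonadotropin subunits and gonadotrope regulators; activin, inhibin and bone morphogenetic protein signalling; secreted antagonists of these; responses to gonadotropin-releasing hormone; steroid receptors and targets; GATA factors; thyrotrope genes; secretory granule genes; voltage-gated channels; other hormones; stem cell genes, which are the stem cell markers; ribosomal proteins; mitochondrial genes; and the markers of each cell type.

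The rule for named genes, fixed before the data were examined, took Gata2, Fshb, Grem1, Lhb, Cga and Gnrhr, the 10 called genes with the largest fall and the 10 with the largest rise in gonadotropes (mean of at least 10 CPM, no overlap between groups), every called list member or otherwise the 2 of each list with the smallest p, and the 3 called genes per direction with the smallest adjusted p in each other cell type. It named 49 genes in gonadotropes. Predicted genes were to be named only where few others qualified. Genes named outside the rule are marked as such.

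Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, other filters on counts (no filter, or a mean of 10 CPM), at least 200 or 1000 genes per nucleus, no doublet removal, no gene left out of clustering, resolutions of 0.5 and 2, equal numbers of nuclei (603) and UMIs (2186612) per library, leaving out genes that change as much in other nuclei, the log of UMIs per nucleus as a term, shares of endocrine nuclei, other thinning depths, and leaving out each library in turn. Added after seeing the data were the library class as a term, clustering without the genes called under that term, gonadotropes without their cluster of low UMI count, and shares of named nuclei. The library class came from average-linkage clustering of Spearman correlations between the summed profiles of 7 cell types other than gonadotropes. Clustering and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

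The tests were tried on simulated counts for the 14320 gonadotrope genes, with 200 genes changed. The size of the simulated class effect was chosen and not estimated from these libraries, so the shares called under it depend on that choice. Without a class effect, edgeR called 62.7% of genes with a log2 fold of 1 and 100% of those with 2 or 4, with 24 false calls. With a simulated class effect that was not in the model, it called 1.49%, 77.6% and 100%, with 0 false calls; with the class in the model it called 56.7%, 98.5% and 100%, with 9 false calls. DESeq2 with the class effect not in the model called 16.4%, 88.1% and 100%, with 0 false calls. The test of the difference between gonadotropes and other endocrine nuclei recovered 14.9%, 94% and 100%, with 9 false calls. In simulated lists, camera with the preset gave an adjusted p of 2.9e-18 for 15 genes lowered together, the estimated correlation 0.0534 and fry 0.0444, and 0 of 20 unchanged lists were called. A simulated lower share of 1 of 14 classes of nuclei was found with an adjusted p of 1.1e-05.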

Results

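Single-nucleus RNA-seq was done on pituitaries of male mice aged 8 to 10 weeks that were either controls or carried a conditional knockout (cKO) of Gata2, a zinc finger transcription factor, in gonadotropes, the cells that make follicle-stimulating and luteinizing hormone. The series title links the knockout to a lack of follicle-stimulating hormone and to a loss of gremlin, so the comparison asked which transcripts and cell types differed between these glands, and whether a difference was particular to gonadotropes. Each library came from a separate mouse, and libraries are named here by group and mouse number. Count matrices of 3 control mice (2, 8 and 9) and 2 cKO mice (3 and 7) were compared. Control 2 held 53351454 UMIs over 15092 barcodes, control 8 held 69260532 over 14514 and control 9 held 83880299 over 13361. The library labelled cKO 3 held 66938625 UMIs over 20550 barcodes and that labelled cKO 7 held 65792897 over 18058. After removal of shallow barcodes and doublets, 68609 nuclei formed 30 clusters, of which 27 were named by markers as 13 classes of cells. The 2 gonadotrope-like clusters held 662, 1112 and 902 nuclei in controls 2, 8 and 9, and 687 and 603 nuclei in cKO 3 and cKO 7.

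Gata2, the targeted gene, was not lower in the libraries labelled cKO. In gonadotrope-like nuclei it stood at 44.5, 58.9 and 62 CPM (UMIs scaled to the same total per sum) in controls 2, 8 and 9, and at 96.8 and 99.2 CPM in cKO 3 and cKO 7. The means were 55.1 ± 9.34 CPM (SD, n = 3) and 98 ± 1.72 CPM (SD, n = 2), a log2 fold of 0.67 (SE 0.21) that was not past the threshold (edgeR adjusted p = 0.848). Within the classes of libraries described below, the log2 ratio was 0.89 in class A and 0.71 in class B. Thyrotrope-like nuclei held 62.4 ± 24.1 and 70.3 ± 11.1 CPM of Gata2, and somatotrope-like nuclei 10.7 ± 3.66 and 10.6 ± 4.63 CPM, in control and cKO libraries. Gata2 lies on chromosome 6 from 88193891 to 88207032 on the plus strand (GRCm38). Which part of the gene was deleted is not given in the sources used here, and UMIs from outside that part do not check the genotype, so these libraries are called cKO only by their labels.

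In gonadotrope-like nuclei, Grem1, which encodes the secreted antagonist of bone morphogenetic proteins gremlin 1, was almost absent from the libraries labelled cKO. It stood at 57.6, 71.8 and 43.2 CPM in controls 2, 8 and 9 (180, 576 and 255 UMIs) and at 1.86 and 1.83 CPM in cKO 3 and cKO 7 (7 and 4 UMIs). Grem1 fell by 5.14 on the log2 scale (SE 0.40, edgeR adjusted p = 0.0178, n = 3 and 2), and it was lower in each cKO library than in every control. It was the only call among 14320 genes tested, with 0 genes higher, while DESeq2 called 13 higher and 42 lower. An unadjusted p under 0.05 was found for 746 genes where 716 would have it by chance. With the library class described below as a term, 1403 genes had such a p. The count of 746 thus does not show that no other gene changed. Grem1 (ENSMUSG00000074934) lies on chromosome 2 from 113746164 to 113758646 on the minus strand. The next smallest adjusted p, just above the threshold, belonged to Gm30382. This long noncoding RNA stood at 14.7 ± 2.5 CPM in controls and 91.9 ± 10.3 CPM in cKO libraries (log2 fold 2.49, SE 0.24). The naming rule did not select it, and it is named because of this value. The Grem1 call ended without control 2 (adjusted p = 0.0927), without cKO 3 (0.252) or without cKO 7 (0.188), at log2 folds of -5.01, -4.99 and -5.24; over all alternatives its adjusted p ranged from 3.1e-16 to 0.252.

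The libraries also split in a way that their groups do not explain. Clustering of the summed profiles of 7 cell types other than gonadotropes set control 8 and cKO 3 (class B) apart from control 2, control 9 and cKO 7 (class A), with this whole split in 6 of the 7 types. The median nucleus gave 56 and 60.9 detected genes per 100 UMIs in class B, and 49, 45.4 and 45.5 in class A. No label gives a batch, so the class was defined from the data and is no group of the study. Within class A, the log2 ratio of Grem1 was -4.18 (CPM + 1), and within class B it was -4.67. With the class as a term in the model, a choice made after seeing the data, Grem1 had a log2 fold of -5.20 (edgeR adjusted p = 0.000444), and 15 genes were higher and 34 lower.

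The gonadotropin genes had lower means in the cKO libraries, and none of these differences passed the test in the model fixed for it. On counts simulated with a class effect of a chosen size that was not in the model, that test called 1.49% of genes with a log2 fold of 1. A missing call is thus no evidence against a change of that size. Fshb, the beta subunit of follicle-stimulating hormone, stood at 5331.2 ± 944.7 CPM in gonadotrope-like nuclei of controls (SD, n = 3) and at 2921.4 ± 1363.4 CPM in cKO libraries (SD, n = 2), with no overlap between the groups (log2 fold -1.02, SE 0.44, edgeR adjusted p = 0.947). Its log2 ratio was -0.46 in class A and -1.44 in class B. Lhb, the beta subunit of luteinizing hormone, stood at 128, 176.8 and 1219.6 CPM in controls 2, 8 and 9 and at 205.5 and 100.6 CPM in cKO 3 and cKO 7, so its log2 fold of -1.90 (SE 0.91, edgeR adjusted p = 0.954) rested on control 9; within class B the ratio was 0.22. Cga, the alpha subunit shared by these hormones and thyrotropin, had 127063.3 ± 32178 and 63638.4 ± 35685.3 CPM (log2 fold -1.15, SE 0.55, edgeR adjusted p = 0.954). Gnrhr, the receptor for gonadotropin-releasing hormone, had 1359 ± 184 and 888.9 ± 41.1 CPM (log2 fold -0.80, SE 0.29, edgeR adjusted p = 0.937). These results depended on the model. With the log of UMIs per nucleus as a term, Fshb (log2 fold -1.80, edgeR adjusted p = 0.0282) and Cga (-2.16, edgeR adjusted p = 0.0414) were called among 416 genes. These calls were not particular to gonadotropins: the same model called Tshb (-2.20, edgeR adjusted p = 0.00378) and Prl (-2.09, edgeR adjusted p = 0.0144), hormones of other lineages, and mt-Nd3 (-1.64, edgeR adjusted p = 0.0215). With no filter on counts, Lhb was called (-1.95, edgeR adjusted p = 0.00289) among 89 genes. Fshb lies on chromosome 2 from 107056140 to 107059656, minus strand. Lhb lies on chromosome 7 from 45420820 to 45421897 and overlaps Ruvbl2 on the other strand, and Cga on chromosome 4 from 34893779 to 34907370 overlaps Platr9. Whether counting used the strand is not given in the sources used here, so the Lhb and Cga values are uncertain to that extent. Fst, which encodes follistatin, had 2 or fewer UMIs in gonadotrope-like nuclei of every library and was not tested.

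**Figure D1:**
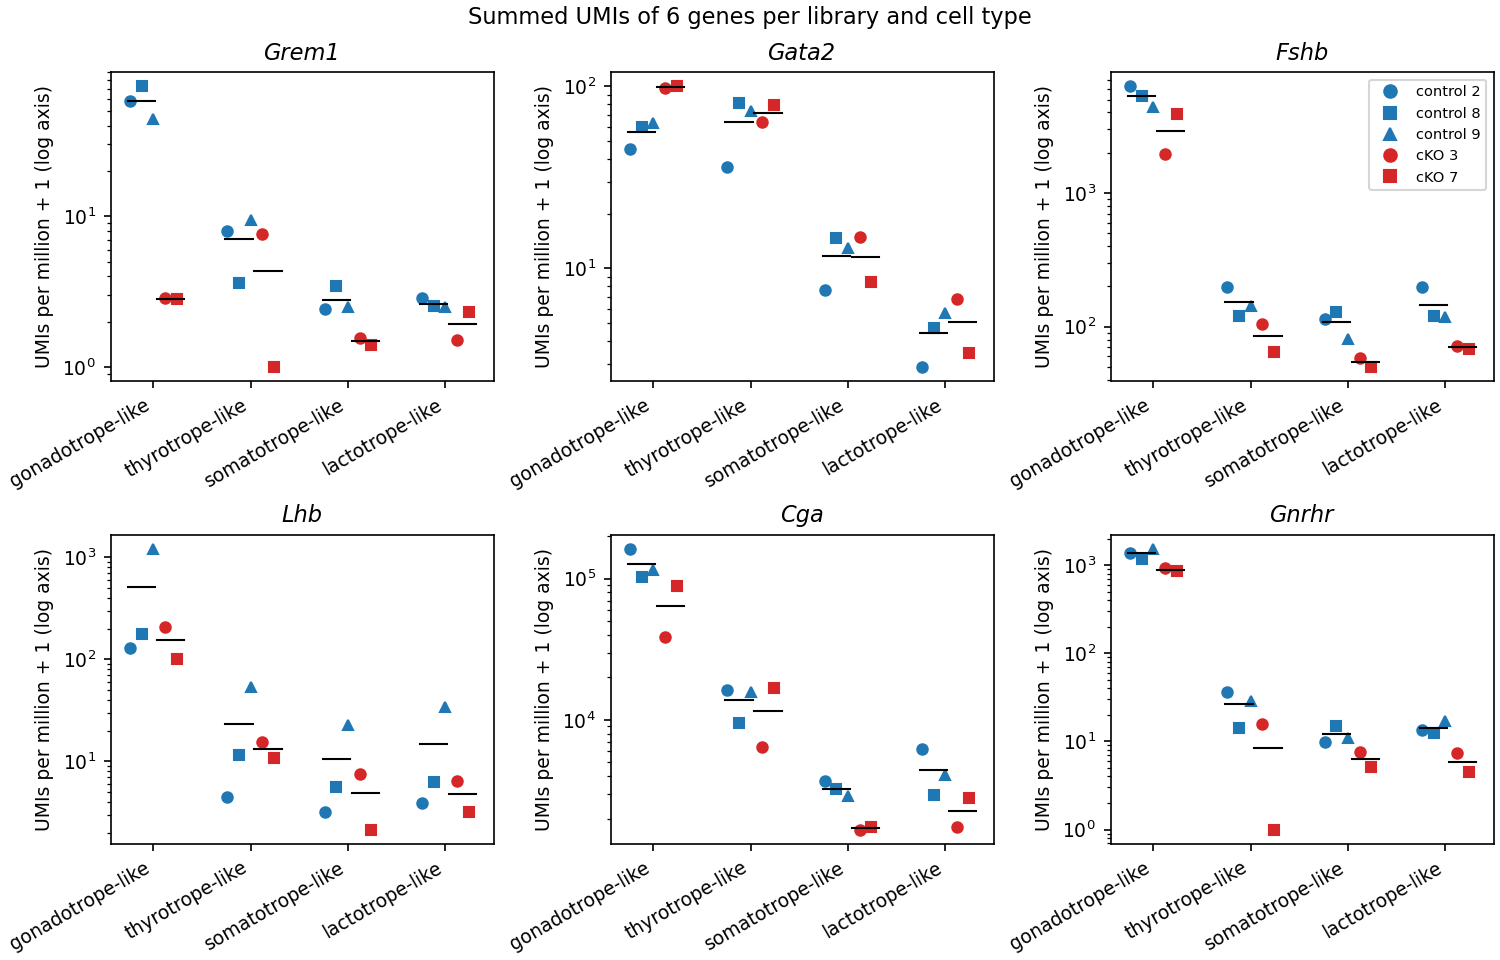
CPM plus 1 (log axis) of Grem1, Gata2, Fshb, Lhb, Cga and Gnrhr, summed over the nuclei of 4 cell types in each library; points are libraries, coloured by group, and bars are the means of 3 control and 2 cKO libraries. In gonadotrope-like nuclei Grem1 lies at 1.86 and 1.83 CPM in the cKO libraries and at 43.2 CPM or more in the controls, while Gata2 lies at 96.8 CPM or more in the cKO libraries and at 62 CPM or less in the controls.

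The share of gonadotrope-like nuclei with a UMI of Grem1 was 4.86% ± 1.34 in controls (SD, n = 3) and 0.0831% ± 0.117 in cKO libraries (SD, n = 2) once each nucleus was thinned to 1000 UMIs. An exact two-sided permutation test gave p = 0.1 for n = 3 and 2, the smallest that 10 splits of the libraries allow. No Grem1 UMI was left in 669 thinned nuclei of cKO 3, which allows a share of up to 0.448% (3 counts of the total), and 1 was left in 602 of cKO 7 (0.166%, exact 95% interval 0.00421 to 0.922%). Somatotrope-like nuclei, used as background, gave 0.168% and 0.0646% for Grem1 in control and cKO libraries. The thinned share in the cKO gonadotropes rests on 1 nucleus and could not be told apart from this background. At 2000 UMIs the cKO shares were 0.351% in gonadotropes (3 nuclei of cKO 3 and 1 of cKO 7) and 0.136% in somatotropes. Some Grem1 above background in the cKO gonadotropes is thus not excluded. Without thinning, the Grem1 shares were 18.7% ± 3.9 and 0.685% ± 0.266, at median depths of 4052, 6790 and 5950 UMIs in controls 2, 8 and 9 and 5770 and 3362 UMIs in cKO 3 and cKO 7; in somatotropes they were 0.923% and 0.193%, at depths of 2839, 4453 and 6022, and 4320 and 3391 UMIs. Fshb UMIs were found in 87.3% ± 3.35 and 75.3% ± 7.5 of thinned gonadotrope-like nuclei (exact permutation p = 0.1, n = 3 and 2), and in 94% and 88.6% without thinning (exact permutation p = 0.1). At 2000 UMIs the Fshb shares were 91.7% ± 3.76 and 83.4% ± 8.55, the groups overlapped (88% in control 8, 89.4% in cKO 7), and the exact permutation p was 0.3 (n = 3 and 2). The difference at 1000 UMIs, -12.1 points, became -6.78 points without cKO 3 (exact permutation p = 0.5, n = 3 and 1). In somatotrope-like nuclei Fshb gave 10.7% and 5.52% thinned, and 37.3% and 17.5% unthinned. Lhb gave 26.7% ± 25.4 and 13.4% ± 7.23 (exact permutation p = 0.8, n = 3 and 2), a difference of -13.3 points that became 1.26 points without control 9, against 1% and 0.466% in somatotropes, and 56.5% and 36.1% unthinned. Gata2 gave 5.76% ± 1.66 and 7.28% ± 0.904 (exact permutation p = 0.4, n = 3 and 2) against 1.07% and 1.08% in somatotropes, and 22.6% and 28.7% unthinned (exact permutation p = 0.5). At 2000 UMIs the Gata2 shares were 10.2% ± 1.78 and 17% ± 0.695 with no overlap (exact permutation p = 0.1, n = 3 and 2, the smallest possible), a difference of 6.82 points against 1.52 at 1000 UMIs. Thinning to 1000 UMIs left out 21 gonadotrope-like nuclei of the controls and 19 of the cKO libraries.

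The fold in gonadotrope-like nuclei was then set against that in all other endocrine nuclei of the same libraries, with the library as a block. The other endocrine nuclei were summed without adjusting for their mix of types. Somatotrope-like nuclei made up 66.1, 42 and 54.7% of endocrine nuclei in controls 2, 8 and 9, and 55.3 and 69.6% in cKO 3 and cKO 7. The difference in fold passed the test for 45 of 19059 genes, 11 with a higher and 34 with a lower fold in gonadotropes. An unadjusted p under 0.05 was found for 1122 genes. The genes named here have the 12 smallest adjusted p or belong to the fixed lists; the 12 were chosen after their values were seen. Grem1 had the largest shift of these, with a difference of -3.62 (SE 0.43, edgeR adjusted p = 0.00195). Ncam2, a cell adhesion molecule, also had a lower fold in gonadotropes than in other endocrine nuclei (-2.22, SE 0.18, edgeR adjusted p = 0.000224). So did Lhfpl3 (-1.85, SE 0.16), Phex, a membrane metallopeptidase (-2.46, SE 0.23), and the lipid phosphatases Plpp3 (-1.85, SE 0.20) and Plpp4 (-2.88, SE 0.31). The same held for Serpine2, a secreted inhibitor of serine proteases (-1.61, SE 0.18), Prkg1, a protein kinase activated by cyclic GMP (-2.29, SE 0.27), and Ndst4, which modifies heparan sulfate (-2.31, SE 0.27). Slit3, a secreted ligand of Robo receptors, had a higher fold in gonadotropes (1.69, SE 0.16, edgeR adjusted p = 0.000311), as did Cacna2d3, an auxiliary calcium channel subunit (1.45, SE 0.17), and Oprm1, the mu opioid receptor (1.25, SE 0.15). The list members Bmper, which binds bone morphogenetic proteins (-1.21, SE 0.17), Pcsk1, a prohormone convertase (-1.32, SE 0.19), and Chga, chromogranin A (-1.60, SE 0.29, edgeR adjusted p = 0.0418), had lower folds in gonadotropes as well. In gonadotrope-like nuclei alone the mean of Prkg1 was 741.7 ± 181.6 CPM in controls and 168.9 ± 62.3 CPM in cKO libraries, that of Serpine2 was 538.6 ± 39.2 and 121.9 ± 26.8, that of Phex was 48 ± 4.24 and 9.52 ± 1.17, and that of Slit3 was 29.3 ± 8.47 and 121.3 ± 46.7. With the library class as a term in the gonadotrope model, 25 of the 45 genes were called there, all 25 in the same direction as the difference. Both fits use the same gonadotrope sums, so the shared direction is no independent check. The differences of Fshb (-0.12, SE 0.24), Lhb (-0.15, SE 0.23), Cga (-0.36, SE 0.34), Gnrhr (0.25, SE 0.19) and Gata2 (0.61, SE 0.18) did not pass the test. For the first 4 of these the test cannot decide whether a fall was particular to gonadotropes. Fshb in somatotrope-like nuclei stood at 1.81, 2.4 and 1.83% of its gonadotrope CPM in controls 2, 8 and 9. In cKO 3 and cKO 7 it stood at 2.93 and 1.25%. If such UMIs are RNA shed by gonadotropes, a fall in gonadotropes alone would appear in both sums and leave little difference. Leaving out cKO 3 left 9 genes, 8 of them among the 45, and ended the calls of Grem1 (edgeR adjusted p = 0.0966), Plpp4, Prkg1, Ndst4, Bmper, Pcsk1 and Chga, whose adjusted p then ran from 0.0645 to 0.385. Leaving out control 2 left 25 genes and ended the calls of Pcsk1 (0.0566) and Chga (0.0962), leaving out control 8 that of Chga (0.0807), and leaving out cKO 7 those of Bmper (0.0673), Pcsk1 (0.074) and Chga (0.0908).

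**Figure D2:**
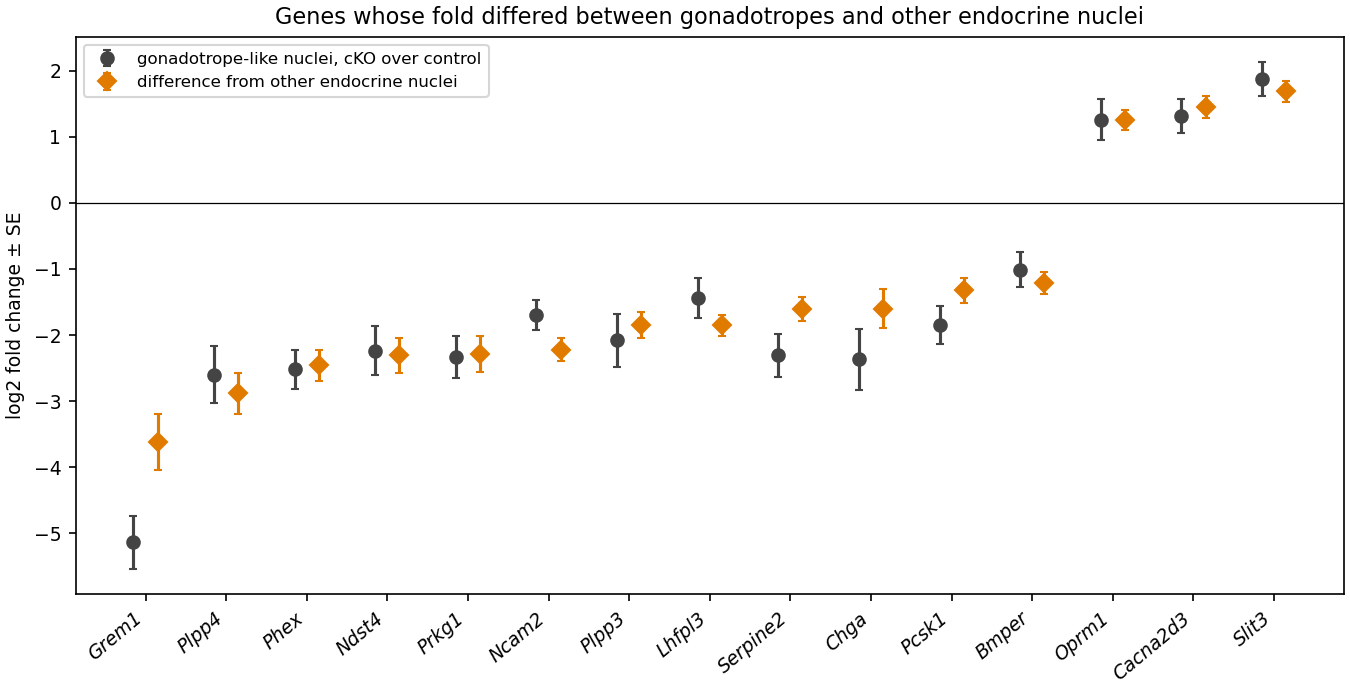
log2 fold change with its SE for 15 genes, cKO over control in gonadotrope-like nuclei (circles) and the difference of that fold from the fold in other endocrine nuclei (diamonds), each from 3 control and 2 cKO libraries. The differences run from -3.62 for Grem1 to 1.69 for Slit3, and their direction is that of the fold in gonadotropes for each gene.

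Of the gene lists fixed before the data were examined, 24 had at least 2 tested members, and 4 of these were called by camera with a preset correlation, all lower in the cKO gonadotropes. No list was called with an estimated correlation, and the count by the preset was 7 without control 8, 8 without cKO 3 and 7 without cKO 7. Among secreted antagonists of bone morphogenetic proteins and activin, 5 of 6 tested members had negative folds (adjusted p = 1.2e-07 by camera in limma, and adjusted p = 0.167 with an estimated correlation). Of these, Grem1 was called over all genes, and Grem1 and Bmper (log2 fold -1.01, SE 0.26) were called adjusted over the list alone. The test fry, which asks whether members move on balance in a single direction, called only this list (adjusted p = 0.0367). Its mean log2 fold was -1.19 and its median -0.48. No test of the list without Grem1 was run, so its calls may rest on Grem1 and do not show a fall of the group. Among secretory granule and exocytosis genes, 16 of 19 members had negative folds (camera adjusted p = 2.2e-05, and adjusted p = 0.167 with an estimated correlation). Adjusted over the list alone, 3 of them were called, namely the granule proteins Scg2 (log2 fold -1.32, SE 0.33) and Chga (-2.37, SE 0.46) and the convertase Pcsk1 (-1.85, SE 0.29), with 0 called over all genes. Among gonadotropin subunits and gonadotrope regulators, 13 of 15 members had negative folds with a median of -0.80 (camera adjusted p = 5.0e-05, and adjusted p = 0.597 with an estimated correlation), and 0 were called either way; the smallest p there belonged to the transcription factors Isl1 (-0.84, SE 0.25) and Pitx1 (-0.69, SE 0.24). Ribosomal protein genes had a median of -0.25, with 77 of 82 members negative (camera adjusted p = 0.00149, and adjusted p = 0.754 with an estimated correlation), and this call ended without control 9 (0.804) and turned without cKO 3 (camera adjusted p = 9.4e-05, higher). Their smallest p belonged to Rpl3 (-0.59, SE 0.34) and Rps19bp1 (-0.55, SE 0.33); the latter matches the symbol rule of the list but encodes a protein that binds a ribosomal protein.

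In the fit to all libraries without the library class as a term, the other lists were not called. Leaving out control 8 gave 7 called lists, so some of them were called there. Activin, inhibin and bone morphogenetic protein signalling had 16 of 28 members positive (camera adjusted p = 0.675), with Bambi, a pseudoreceptor of this family, at -2.32 (SE 0.54) and Igsf1 at -0.91 (SE 0.26). Response genes of gonadotropin-releasing hormone had 12 of 18 negative (adjusted p = 0.166), with Fosb at -1.54 (SE 0.53) and the kinase Prkca at 0.78 (SE 0.26). Steroid receptors and targets had 6 of 9 positive (0.166), with the estrogen receptor Esr1 at 0.50 (SE 0.25) and Tsc22d3 at 0.45 (SE 0.32), and GATA factors and partners had 3 of 5 positive (0.166), with Lmo2 at 0.65 (SE 0.44). Voltage-gated ion channels had 13 of 14 positive (adjusted p = 0.0655), with Kcnip4 at 0.51 (SE 0.25) and Cacna1b at 0.50 (SE 0.26). Thyrotrope genes had an adjusted p of 0.856, with Tshb at -0.96 (SE 0.57) and Thrb at 0.24 (SE 0.20). Mitochondrially encoded genes, read as a sign of cytoplasmic RNA, had 10 of 13 negative (0.0513; called lower with the library class as a term, camera adjusted p = 0.0122, and adjusted p = 0.681 with an estimated correlation), with mt-Nd3 at -1.0 (SE 0.36) and mt-Atp8 at -1.60 (SE 0.84). Hormones of other lineages had 4 of 4 negative (0.166), with Prl at -0.65 (SE 0.67) and Pomc at -0.55 (SE 0.59).

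Markers of other cell types were tested in the gonadotrope sums as well, and none of their lists was called in the fit to all libraries. The camera adjusted p was 0.166 for markers of thyrotropes, somatotropes (Gpr101 -0.60, Pappa2 -0.39), endothelial cells (Cdh5 0.75, Ptprb 0.29) and fibroblasts (Dcn -0.82, Col1a2 -0.44). It was 0.949 for lactotropes (Syndig1 1.33, Agtr1a -0.62), 0.684 for corticotropes (Gpc5 0.72), 0.155 for mural cells (Notch3 0.87, Rgs5 0.42) and 0.675 for macrophages (C1qa -0.81, Cd163 0.19). Melanotropes (Rbfox3 0.68, Oacyl -0.64) and stem cells (Lcn2 -0.76, Rbpms 0.38) each gave 0.845, and erythroid genes (Hbb-bt 0.79, Hba-a1 0.50) gave 0.358. The globin genes are near-identical copies, and how their reads were assigned is not given in the sources used here. Markers of pituicytes (Col25a1 0.66), dividing cells (Mki67 -0.81) and lymphocytes had 1 tested gene each, too few for a set test; Bank1, the tested lymphocyte gene, had a log2 fold of 1.74 (SE 0.55) and was called adjusted over the list alone, which for 1 gene is no adjustment.

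In the 12 other cell types tested, edgeR called 0 genes without a class term, DESeq2 called 6, and 11 were called by edgeR with the library class as a term. In gonadotrope counts simulated with a class effect of a chosen size that was not in the model, 1.49% of genes with a log2 fold of 1 were called. Counts of each of these types were not simulated. The 0 calls do not show that these types were unchanged. The counts at an unadjusted p under 0.05 lay below those chance gives in each of these types, for example 98 in somatotrope-like nuclei where 887.1 would by chance, 230 in lactotropes (753.3) and 396 in pituicytes (408.6). With the class as a term, Inpp4b, an inositol phosphatase, was higher in lactotrope-like nuclei of the cKO libraries, at 112.6 ± 32 CPM against 16.6 ± 2.23 CPM (log2 fold 2.74, SE 0.22, edgeR adjusted p = 0.000349; 0.324 without the term), as was Klhl1 (2.42, SE 0.28). Grin2a, a glutamate receptor subunit, was lower in thyrotrope-like nuclei (-3.14, SE 0.49), with an edgeR adjusted p of 0.0892 without the term. It stood at 79.4 ± 19.5 CPM in controls and 9.54 ± 0.331 CPM in cKO libraries. The cKO values rest on 7 UMIs in cKO 3 and 2 in cKO 7, against 25, 71 and 27 in controls 2, 8 and 9. Their small SD is thus no measure of precision. Thyrotropes also gave Car10 (1.23), mt-Co2 (-1.31), Gm10076 (-2.09) and Gm42418 (-1.29), each with an edgeR adjusted p of 1 without the term. The groups overlapped for Gm10076 and for Gm42418, which stood at 210.2, 3012.9 and 3076 CPM in controls 2, 8 and 9 and at 2817.5 and 278.6 CPM in cKO 3 and cKO 7, with a log2 fold of -0.48 without the term. Melanotropes gave Gm26760 (4.27). Pcsk1 and Chga were lower in stem cell-like nuclei (-1.67, SE 0.23, and -1.82, SE 0.25), and Chga in fibroblast-like nuclei (-1.82, SE 0.34). Control means of Chga were 399.5 CPM in stem cell-like and 114.7 CPM in fibroblast-like nuclei, against 4104.2 CPM in gonadotrope-like nuclei. Those of Pcsk1 were 66 CPM in stem cell-like and 1006 CPM in gonadotrope-like nuclei. Free RNA from other cells was not tested for these genes, so their folds may not belong to stem cells or fibroblasts. All 11 were named after their values were seen. Transcripts of gonadotropes were also low in other cell types of the cKO libraries: in somatotrope-like nuclei Fshb had a log2 fold of -1.05 (SE 0.30), Cga -0.96 (SE 0.35), Spp1, which led the gonadotrope-like clusters, -1.71 (SE 0.35) and Grem1 -1.90 (SE 0.43), with an adjusted p of 1 for each. Without cKO 7, 404 genes were called in these types, without cKO 3 22, and without control 8 1.

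No cell type differed in its share of nuclei at the threshold, in edgeR's test with 14 classes of nuclei. Gonadotrope-like nuclei made up 7.2% ± 1.67 of control nuclei (SD, n = 3) and 4.1% ± 0.11 of cKO nuclei (SD, n = 2), with a log2 fold of -0.81 (SE 0.55, edgeR adjusted p = 0.687; exact permutation p = 0.2 for n = 3 and 2). As a share of endocrine nuclei they were 5.97, 13.4 and 8.97% in controls 2, 8 and 9 and 9.12 and 4.74% in cKO 3 and cKO 7, a log2 fold of -0.45. Somatotrope-like nuclei made up 44.3% ± 16.4 and 42.8% ± 26.1, and lactotrope-like nuclei 13.5% ± 2.82 and 9.58% ± 1.8. The somatotrope, lactotrope and melanotrope clusters that held most nuclei of a library differed between classes A and B. Unnamed nuclei were 42% of cKO 3, against 1.02, 6.33 and 5.96% of controls 2, 8 and 9 and 0.927% of cKO 7. Most of them lay in a cluster of 7230 nuclei, 6982 of them from cKO 3, at 0.52 of the median UMI count of their library; its best match was melanotrope, but thresholds set after seeing the data left it unnamed. Its nuclei count in the total of cKO 3 whatever their name, which lowers the shares of the other types there. The smallest unadjusted p over the 14 classes was 0.0765, so 0 were under 0.05. Without cKO 7 the unnamed class was called, the 1 call among these fits.

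**Figure D3:**
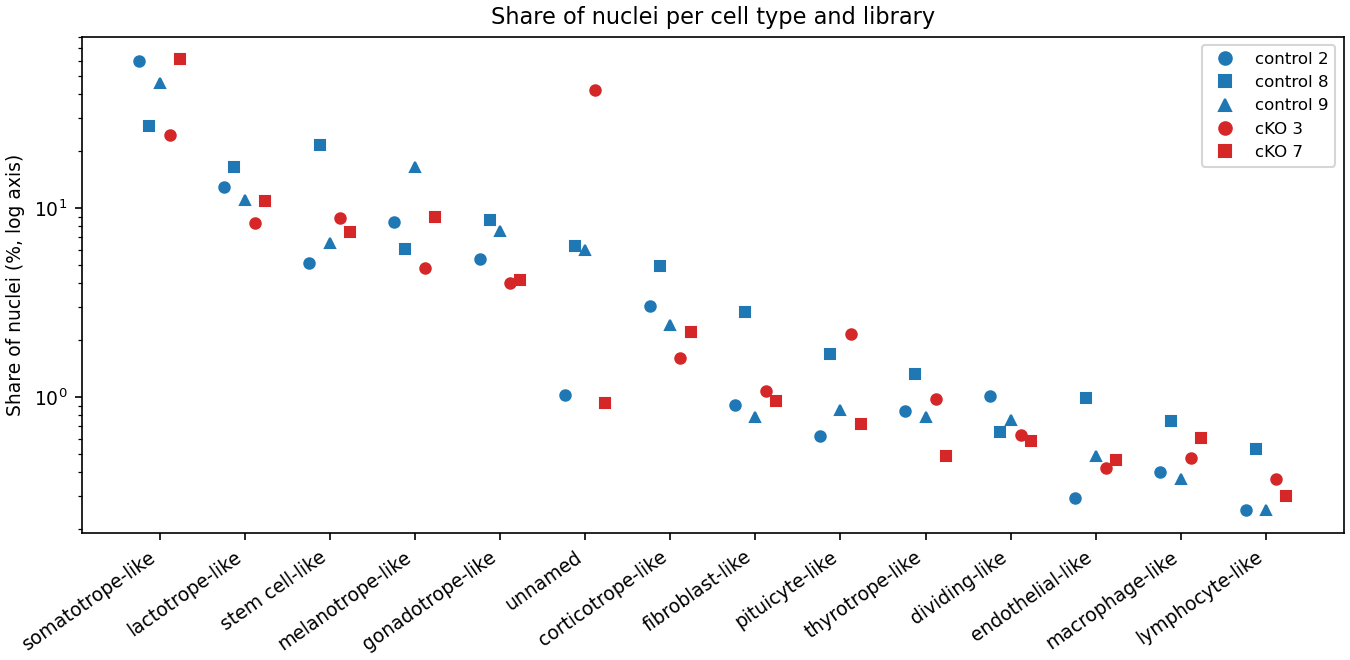
Share of all nuclei (percent, log axis) of each cell type named by markers, and of unnamed nuclei, in each of 3 control (blue) and 2 cKO (red) libraries. Gonadotrope-like nuclei make up 5.39 to 8.68% of controls and 4.02 and 4.17% of cKO libraries, and unnamed nuclei 42% of cKO 3.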

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

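The difference in fold between gonadotropes and other endocrine nuclei and the fit with equal nuclei and UMIs per library were planned, but their use as tests of explanations, and the tests of library class, splits, labels, deleted part, free RNA and scaling, were chosen after the results were seen. In 15 named genes, the cKO effect in gonadotropes differed from that in other endocrine nuclei of the same libraries by this test. The differences were -3.62 for Grem1, -2.88 for Plpp4, -2.46 for Phex, -2.31 for Ndst4, -2.29 for Prkg1, -2.22 for Ncam2, -1.85 for Lhfpl3, -1.85 for Plpp3, -1.61 for Serpine2, -1.60 for Chga, -1.32 for Pcsk1 and -1.21 for Bmper, and 1.69 for Slit3, 1.45 for Cacna2d3 and 1.25 for Oprm1. Groups of 3 and 2 libraries are too small for a test of single outlying libraries.

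Grem1 was lower in gonadotropes of both cKO libraries than in every control, and depth, the library class and free RNA are the technical explanations that could account for it. With the same number of nuclei and UMIs per library the log2 fold was -5.07 (SE 0.44). Random thinning keeps the expected CPM, so this shows only that the fold remained at equal counts. It cannot decide on other effects of depth. Within the classes the weaker log2 ratio was -4.18, which argues against the library class as the whole cause. Relative to other endocrine nuclei of the same libraries the difference was -3.62, which argues against free RNA as the whole cause. The real split of the libraries gave 1 called gene and 3 of the 10 splits gave as many, with 698 as the highest of the others, and 10 splits are too few for a share under 0.05. The split with 698 genes set control 8 and cKO 3 apart, which is the library class, and points to a structure of the samples; with the class as a term Grem1 kept an adjusted p of 0.000444 in edgeR. A loss of Grem1 in gonadotropes that follows the labelled genotype remains a hypothesis. Chance stays open with 2 cKO libraries, as do effects of depth that thinning cannot test.

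Gata2 UMIs were not lower in the libraries labelled cKO. A single wrong label could hide a loss. Each cKO library lay apart from every control in Grem1, with 23.2 times more in the lowest control than in the highest cKO library. This checks the labels only if the knockout lowers Grem1, which is the result in question, so a wrong label stays open. Free Gata2 RNA could raise the level in gonadotropes of the cKO libraries, but these held at least 6.96 times the Gata2 level of somatotropes. UMIs from outside the deleted part of the gene stay open: the log2 fold of all Gata2 UMIs was 0.67, and the tables hold 1 count per gene, so a transcript lacking the deleted part is not separable from a full one. Whether the protein was lost was not tested.

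Fshb, Lhb, Cga, Spp1 and Gnrhr had negative log2 folds in 24 of 25 values over 5 other cell types (somatotropes, lactotropes, corticotropes, melanotropes and stem cells), from -2.00 up to 0.29, the exception, for Gnrhr in corticotropes. Free RNA from gonadotropes may account for part of this, since the folds lay a median of 0.22 from those in gonadotropes (median SE 0.37), but Gnrhr matched less well, at 0.29 in corticotropes and -1.54 in lactotropes against -0.80 in gonadotropes. Grem1 differed from them: its fold in somatotropes was 3.23 (SE 0.59) above that in gonadotropes. The folds came from separate fits to the same libraries, and this SE takes them as independent. The level of Grem1 in somatotropes was 30.9 and 21.9% of that in gonadotropes of cKO 3 and cKO 7, against 2.47 to 3.53% in controls. With only 7 and 4 Grem1 UMIs in those gonadotropes its source stays open. Scaling of whole libraries stays open as well, since TMM within each type sets the median fold of all genes near 0 (-0.04 at its lowest) and that value decides nothing. A change of these transcripts in the gonadotropes that shed them, or in the number of gonadotropes, stays open as the biological explanation and was not tested apart.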

How the results depend on the processing

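The library class term, clustering without genes called under it, the low-UMI cluster and shares of named nuclei were alternatives chosen after seeing the data. No paired analysis was possible because the mouse numbers are not shared between the groups. Clustering without genes called in gonadotropes repeated the main clustering, since Grem1, the only call, was already left out; the added alternative with 49 genes stands in for it. The count of called gonadotrope genes, 1 as reported, was 2 with RLE size factors, 2 with no gene left out of clustering, 2 at resolution 2 and 2 without genes that change as much in other nuclei; the extra gene was Gm30382. It was 55 with DESeq2, 89 with no filter on counts, 416 with the log of UMIs per nucleus as a term and 49 with the library class as a term, and 0 to 1 when a library was left out. The cause of these rises was not tested. Grem1 was among the called genes in 18 of 21 alternatives. In other cell types DESeq2 called 6 genes and the class term 11, and leaving out a library gave 0 to 404. The difference between gonadotropes and other endocrine nuclei gave 9 to 46 genes without a library, and shares of nuclei 0 to 1. Without a cKO library, the lone one left is assumed to vary as controls do.

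Lists called fell to 0 with an estimated correlation and to 1 with fry, and were 5 to 8 without a library and 5 with the class term, which added mitochondrially encoded genes (0.0122); the ribosomal list ranged from 5.1e-22 to 0.804 and turned higher without cKO 3 (9.4e-05). The difference in share of nuclei with a UMI was -5.4 points for Fshb, -18 for Grem1 and 6.08 for Gata2 with no thinning, and -8.32, -8.24 and 6.82 at 2000 UMIs. Without a library it ranged from -17.4 to -6.78 for Fshb and from -22.4 to 1.26 for Lhb. Uncalled genes whose log2 fold turned were Col1a2 (0.43), Agtr1a (0.15) and Pappa2 (1.21) at 200 genes per nucleus, Ptprb (-0.01) and Rbpms (-0.51) at 1000, Col1a2 (0.10) and Pappa2 (0.39) with doublets, Hbb-bt (-0.36), Hba-a1 (-1.0) and Tsc22d3 (-0.02) with the UMI term, and Cd163 (-0.20) with the class term. Without a library, folds ranged from -1.97 to 0.02 for Prl, -2.45 to 0.87 for Cd163, -1.26 to 0.07 for Pomc, -1.09 to 0.05 for Oacyl, -1.99 to 0.05 for Mki67, -0.19 to 0.56 for Ptprb, -1.30 to 0.19 for Col1a2, -2.56 to 0.17 for C1qa, -0.49 to 1.49 for Hbb-bt, -0.94 to 1.22 for Hba-a1 and -0.04 to 0.85 for Tsc22d3. Differences from other endocrine nuclei ranged from -0.51 to 0.28 for Fshb and -0.47 to 0.37 for Lhb. The cause was not tested. Fshb (adjusted p 0.0282 in edgeR) and Cga (0.0414) were called only with the UMI term, which also called Tshb, Prl and mt-Nd3, and Lhb (0.00289) only with no filter on counts. In gonadotropes alone, Grem1, Fshb, Lhb, Cga, Gnrhr and Gata2 kept their direction in every alternative. The call of Grem1 was lost without control 2, cKO 3 or cKO 7, and in the difference from other endocrine nuclei that of Chga was lost with RLE size factors (0.0513).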

Other observations

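Some clusters outside the gonadotropes came mostly from a single library. A pituicyte-like cluster of 302 nuclei, led by Col25a1, Lrrtm3 and Ctnna3, held 292 nuclei of cKO 3 at 0.53 of the median UMI count. A somatotrope-like cluster of 28 nuclei, led by the interferon response genes Ifit1, Rsad2 and Herc6, held 23 nuclei of control 2. A cluster of 324 unnamed nuclei led by globin genes together with the fibroblast genes Dcn and Col3a1 held 166 nuclei of control 8. The barcode list of cKO 17 held 24281 barcodes; its counts were not analysed here.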
